A study of Triticum aestivum with 18 samples.

How the data were processed

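RNA was extracted from leaves and grains of wheat at the grain filling stage, and libraries of poly(A) RNA were sequenced in pairs of reads, per the labels. The 18 libraries fell into 6 groups of 3 by tissue and treatment as the labels give them. The labels do not say whether the 3 libraries of a group came from separate plants, so the p-values measure the spread between these samples. They give groups the same library numbers but no plots or days that would pair them.

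The deposited table held gene FPKM (fragments per kilobase of transcript, relative to the mapped fragments of the library), which the authors computed before deposition, and per the labels the tools were HISAT, StringTie and edgeR, without versions. The column sums of FPKM ranged from 409211 to 779076. Of 115478 loci, 97029 carried a gene name in the TGACv1 form or another name, and 18449, here called unnamed loci, carried none. The table gave a description for 12901 loci, and only these could enter the gene lists or be named. Many loci are assembled identifiers that also carry a gene name. Reads of homoeologs on the A, B and D genomes can be assigned to one another, so the chromosome arm of a single copy is uncertain. The strand of the libraries is not stated. Positions were not analysed here, and chromosome arms are those in the gene names.

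Read counts were not used here, so the depth was unknown and the precision of each value was taken from the spread between libraries alone. Relative depth was recovered from values under an FPKM of 0.1, where the ratio of the same gene between 2 libraries piles up at the ratio of a single read. It lay between 0.813 and 1.06 of control leaf library 1, and at 0.870 in shaded grain library 2, where 7.00% of the genes compared lay near this ratio. The low number of genes in that library thus did not come with a low depth over all loci. Unnamed loci took 89.9% of its FPKM sum, which left a smaller share for named loci than in any other library.

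Each tissue was analysed on its own with limma 3.58.1 in R 4.3.3. A gene was tested if its FPKM was at least 1 in at least 3 of the 9 libraries of the tissue. FPKM was scaled between libraries by the median ratio to the geometric mean over genes above 0 in all 9 libraries (46922 genes in leaf and 44129 in grain), and log2(scaled FPKM + 1) was fitted with 1 mean per group. Comparisons were tested as contrasts with moderated variances and a trend on mean level. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and calls of at least 2-fold were counted beside it. Log2 values are differences of group means with their moderated SE, and scaled FPKM values are means ± SD with n = 3. The effect of partial removal in leaf minus that in grain was tested in a fit of 12 libraries, over genes with FPKM of at least 1 in at least 3 libraries of each tissue. A gene listed at 0 in all libraries of a group is given no fold.

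There were 36 gene lists, fixed as text patterns on gene descriptions before the data were examined, as were the comparisons, the filters, the test and the settings tried, except where stated. Lists with at least 5 tested members were tested with limma camera at its preset correlation of 0.01, adjusted over the lists of a comparison. This left 31 lists in leaf, 32 in grain and 26 in the contrast of leaf with grain. Lists of fructan metabolism, gibberellin, and amylase and protease inhibitors with serpins were too small in all of them. Storage proteins and abscisic acid were too small in leaf, and WRKY factors in grain. Camera compares a list with all other genes. With an estimated correlation, camera kept the jasmonate list in leaf after partial removal and in the contrast of leaf with grain, and no other list. With lists extended by GO and KEGG names the first of these was lost (adjusted p = 0.131) and the second had adjusted p = 0.0477. Limma fry tests whether the genes of a list move on balance one way, and its mixed form whether they move in either direction, without comparing them with other genes. The patterns of 6 lists matched 120 members by accident, such as inhibitors of proteases in the list of proteases. The lists were used as fixed, and counts without these members, removed from the descriptions after the data were seen, are given beside them where the number of calls or the verdict of camera given in the text changes. Both versions had been computed before the fixed lists were kept as the main ones. The list of protein folding held mainly isomerases, and the jasmonate list mainly lipoxygenases.

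Genes were named by a rule fixed before the data were examined. It took, among genes with an informative description, the 6 largest rises and the 6 largest falls of those calls whose groups did not overlap and whose higher group mean was at least 5 scaled FPKM, once per description. For the contrast of leaf with grain the condition on overlap does not apply, and the level was first taken as the mean over all 12 libraries. It was corrected to the highest group mean, as the rule says, after the results had been seen, and 5 genes are named by it. It also took from each list the 2 called members with the highest mean and the 1 with the largest change, or the member with the highest mean where none was called. Among unchanged genes, 3 libraries lie all on one side of 3 others in 10% of cases.

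The test was tried on simulated data with the fitted spread, in which 200 genes per comparison were changed. In leaf, 2-fold changes were recovered in 38% of cases after partial removal and in 48% after whole removal, and in grain in 64% after partial removal and 66% after shading. Comparisons within a tissue were simulated from the same levels and spread, so differences between them come from the draw of genes and noise. With so few changed genes the adjusted threshold was stricter than in data with many calls. Recovery was lowest, at 27%, for the contrast of leaf with grain. There each gene was simulated at the same level in leaf and grain, unlike in the data, so this rate need not hold for the real contrast. Changes of 4-fold were recovered in 82% to 91% over all 7 tests. The simulated noise was independent between genes and equal between libraries, which real libraries need not be. For the genes shared by 2 comparisons, simulated groups without any change shared 0, but since they call next to nothing this says nothing about shared controls. A simulation added after the results were seen moved the effects of partial removal to other genes of like level and kept the controls shared. It called 5076 genes in leaf and 2894 in grain after partial removal, against 799 and 13 in the data, so it is not a matched baseline. In it 20.1% of the calls after partial removal were shared in the same direction in leaf and 8.22% in grain, against 84.7% and 61.5% in the data, with means of 1019 genes shared in the same direction and 678 in opposite directions in leaf, against 677 and 3.

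Settings fixed before the data were examined were no scaling, quantile normalization, a pseudocount of 0.1, no filter, a filter at an FPKM of 5, no variance trend, a block for the library number, named loci only, the libraries of the compared groups only, other set tests, and leaving out each library in turn. Settings added after seeing the data were weights per library, leaving out control leaf libraries 2 and 3, leaving out control grain library 1 with shaded grain library 2, the lists without accidental members, lists extended by GO and KEGG names, and tests of GO terms. The test of scaling for unnamed loci first used their share among calls. That share was 37.7% without scaling and 59.2% with quantile normalization, and after it had been seen the test was replaced by the number of the same loci that kept their call. The test of shaded grain library 2 first used the median change, without that library, of genes called with it, a set already chosen for its falls, and was replaced by the share of rises among genes called anew. The simulation beside the reserve genes of grain was also added after their share had been seen. The reference table of gene symbols shared no identifiers with these loci and was not used here.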

Results

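Poly(A) RNA from leaves and grains of wheat (Triticum aestivum) at the grain filling stage was sequenced in 18 libraries that formed 6 groups of 3. Leaves came from normally growing plants, from plants with 0.5 of the spike taken off (partial removal), and from plants with the whole spike taken off (whole removal). Grains came from normally growing plants, from spikes after partial removal, and from plants whose spike was shaded and whose leaves were all removed. Taking off spikes lowers the demand of the grains on the leaves, and shading with removal of leaves lowers the supply to the grains and also takes light from the spike. Demand and supply were not measured here. Shading was applied only together with removal of leaves, so their effects cannot be told apart. No group was cut without losing spike or leaves. Effects of the cutting itself therefore cannot be told apart from those of demand or supply. The values were gene FPKM for 115478 loci, so the number of reads per library was unknown and no interval from counting reads could be given. The steps between low FPKM values nevertheless gave the depth of each library relative to control leaf library 1, and this lay between 0.813 and 1.06.

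The libraries differed in what their FPKM fell on. Of the FPKM sum, loci without a gene name took 15.9% ± 3.30 (SD, n = 3) in control leaves, 29.7% ± 3.84 (SD, n = 3) after partial removal and 30.9% ± 4.53 (SD, n = 3) after whole removal. Plastid and mitochondrial rRNA took 1.95% ± 1.14, 7.68% ± 1.88 and 7.64% ± 1.21 in the same 3 groups. In shaded grain library 2, unnamed loci took 89.9% of the FPKM sum, 12276 genes reached an FPKM of 1 and the scaling factor was 0.226, while each of the other 17 libraries had at least 36709 such genes. Control grain library 1 had 55.4% on unnamed loci. Transcripts annotated with nutrient reservoir activity, a wider set than the storage protein list, made up 0.0683% and 0.0974% of FPKM in control leaf libraries 2 and 3, against 0.00569% in control leaf library 1 and at most 0.00532% in the 6 leaf libraries from treated plants.

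**Figure D1:**
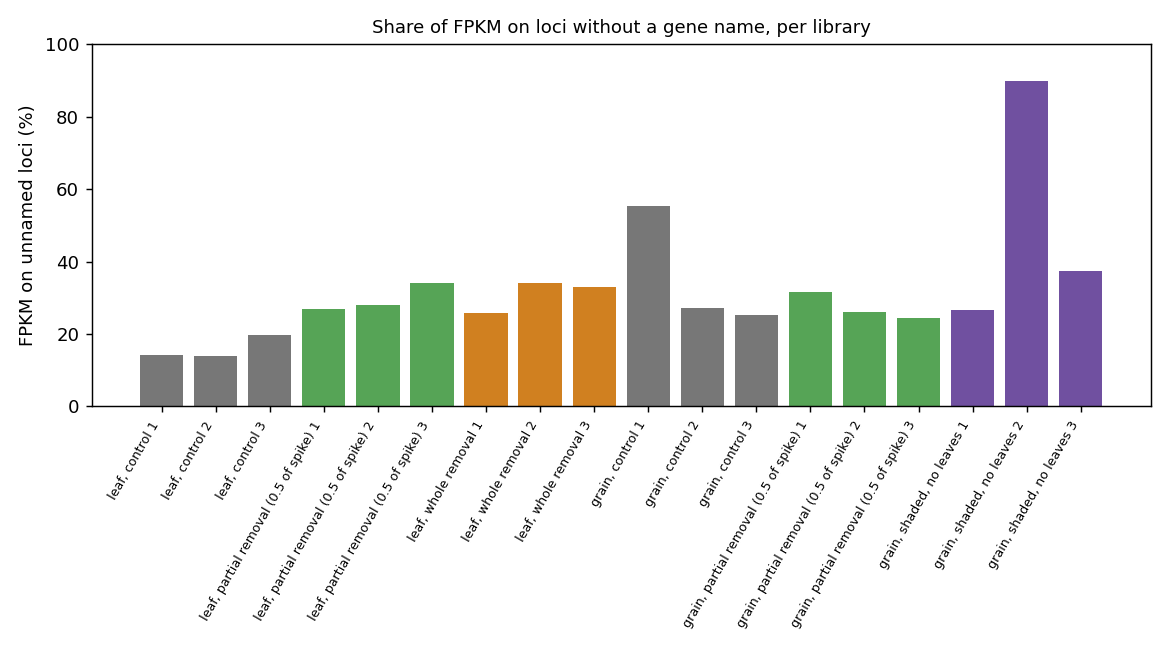
Percent of each library's FPKM sum on loci without a gene name, 1 bar per library, coloured by group. Shaded grain library 2 reached 89.9% and control grain library 1 reached 55.4%, and the 6 leaf libraries from plants without part or all of the spike lay between 25.8% and 34.2%, above the 3 control leaf libraries at 13.9% to 19.7%.

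The comparison of leaves after partial removal of the spike with control leaves asked how leaf transcripts changed when the demand for assimilate was reduced in part. Probable sucrose-phosphate synthase 4, of the family that catalyses the committed step of sucrose synthesis, fell to 8.07 ± 2.75 scaled FPKM from 26.2 ± 3.59 in the copy on 4AL (MSTRG.35971, log2 -1.63 ± 0.27 SE, adjusted p = 0.0212). The copy on 4DS (MSTRG.42906) fell by 1.21 ± 0.22 on the log2 scale. Lipoxygenase MSTRG.11562 on 2AL fell to 0.960 ± 0.268 from 5.57 ± 1.17 (log2 -1.74 ± 0.16, adjusted p = 0.00448). Its family oxygenates fatty acids, which can lead to jasmonate, but its description does not say whether this gene serves jasmonate synthesis. Lipoxygenase MSTRG.8761 on 1DL fell by 0.74 ± 0.14. Probable galactinol-sucrose galactosyltransferase 6 (MSTRG.77407), an enzyme of raffinose synthesis, fell by 1.76 ± 0.16. Malate synthase (MSTRG.16081, 2BL), a glyoxylate cycle enzyme, fell by 1.58 ± 0.28. In the other direction, chloroplast thioredoxin F (MSTRG.26631, 3B), which links the light reactions to the Calvin cycle enzymes, rose to 116 ± 23.9 from 53.0 ± 5.79 (log2 1.11 ± 0.22, adjusted p = 0.0492).

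Other genes that fell were the long-chain-alcohol oxidase MSTRG.274 on 1AL (log2 -1.93 ± 0.23), the DELLA protein RHT-1 (MSTRG.42729, log2 -1.68 ± 0.18), a repressor of gibberellin responses, and the auxin-responsive protein MSTRG.26783 on 3B (log2 -0.61 ± 0.12). Chloroplast glycerol-3-phosphate acyltransferase (MSTRG.9046, 1DL) rose by 0.93 ± 0.18. The photosystem II protein Psb28 (MSTRG.49979, 5BL) rose by 0.88 ± 0.17 and the Cu-Zn superoxide dismutase 3 (MSTRG.36628, 4AS) rose by 0.77 ± 0.13 (log2 ± SE, n = 3 per group). A cytokinin riboside monophosphate phosphoribohydrolase, the enzyme that releases active cytokinins (MSTRG.49671, 5BL), passed the test at a mean of 3.22 scaled FPKM with all 3 controls listed at 0, so no fold is given.

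Of the 23 genes of the jasmonate list that were measured, most of them lipoxygenases, 5 fell and 18 did not pass the test over all genes, and 15 fell when adjusted over the list alone. The list lay lower than other genes by limma camera (median log2 -0.54, adjusted p = 7.43e-15). With an estimated correlation it had adjusted p = 0.0211, but when the list was extended by GO and KEGG names to 45 genes, a setting added after seeing the data, the median was -0.26 and adjusted p = 0.131 with an estimated correlation. Of 37 genes of sucrose metabolism and transport, 2 fell over all genes tested and 6 when adjusted over the list alone. Camera placed this list lower (adjusted p = 1.27e-05), and adjusted p = 0.276 with an estimated correlation. Of 76 genes of the light reactions 1 rose, and the list lay higher (median log2 0.38, camera adjusted p = 8.18e-05, and adjusted p = 0.778 with an estimated correlation). The 30 chlorophyll synthesis genes (median log2 0.32) and the 31 starch synthesis genes (median log2 0.27) also lay higher by camera, with no gene called in limma and 1 starch synthesis gene higher when adjusted over the list alone. They had adjusted p = 0.778 and adjusted p = 0.651 with an estimated correlation. Starch branching enzyme IIa (MSTRG.11210, 2AL) stood at 29.9 ± 1.86 against 18.3 ± 4.40 (adjusted p = 0.142). The 69 auxin genes lay lower (1 fell, 3 when adjusted over the list alone, camera adjusted p = 0.000487, and adjusted p = 0.0721 with an estimated correlation). Ethylene genes also lay lower by camera (median log2 -0.19, adjusted p = 0.0475, and adjusted p = 0.651 with an estimated correlation). The Calvin cycle list (median log2 0.32, but -0.0441 with quantile normalization), pathogenesis-related proteins (0.21, but -0.0682 without scaling) and ribosomal proteins (0.0837, but -0.19 without scaling and -0.0251 with quantile normalization) lay higher by camera. With an estimated correlation these 3 had adjusted p = 0.819, 0.753 and 0.819. Without members matched by accident the pathogenesis-related list held 12 genes and was not called (camera adjusted p = 0.290), while the autophagy list was (42 genes, camera adjusted p = 0.0407, and adjusted p = 0.755 with an estimated correlation).

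In all, limma called 799 of 48696 genes, 535 higher and 264 lower, of which 646 changed at least 2-fold. Without scaling the balance turned, with 577 higher and 1469 lower, as the median of all genes then shifted by -0.23. Among the higher ones 475 were loci without a gene name and 60 had one, and among the lower ones 32 had none and 232 had one. The share of FPKM on unnamed loci was larger in each treated leaf library than in each control leaf library, as given above. The count depended on single libraries: it was 186 without control leaf library 1, 198 without control library 2, and 415, 344 and 262 without libraries 1, 2 and 3 of the treated leaves. Of the 14 genes named here as called, 5 kept their call under every setting tried that was fixed before the data were examined, and none changed direction. Under both no scaling and quantile normalization 9 kept it, and 5 did when each library was left out in turn.

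The comparison of leaves after removal of the whole spike with control leaves asked what the leaf transcripts did once the main sink was gone. Among called genes that met the naming rule, which needs a description, the largest rise was that of sucrose:fructan 6-fructosyltransferase (MSTRG.34298, 4AL), which builds fructan storage sugars from sucrose and stood at 439 ± 91.9 scaled FPKM against 21.4 ± 16.6 in controls (log2 4.85 ± 0.81 SE, n = 3 per group, adjusted p = 0.00413). Control leaf library 3 was lower than the other 2 controls, and without it the log2 change was 3.76. Some genes of starch metabolism rose, among them starch branching enzyme IIa (MSTRG.11210), to 57.5 ± 1.76 from 18.3 ± 4.40. Alpha-glucan phosphorylase 1 (MSTRG.44132, 5AL) rose to 33.7 ± 5.07 from 6.47 ± 1.60. Of the genes of sucrose metabolism and transport, 15 of 37 fell, among them sucrose synthase MSTRG.51537 on 5DL, to 5.21 ± 2.28 from 31.9 ± 6.17. Probable sucrose-phosphate synthase 4 on 4BS (MSTRG.39324) fell to 7.33 ± 2.80 from 36.7 ± 5.59. Of the ribosomal protein genes 149 of 226 rose, and of the phosphate response genes 26 of 48 fell. The sulfolipid synthesis enzyme SQD2 (MSTRG.27181, 3B) fell to 5.54 ± 2.23 from 95.5 ± 3.56 (log2 -3.95 ± 0.26, adjusted p = 6.93e-05).

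Of 226 measured ribosomal protein genes, cytosolic and organellar together, 149 rose, none fell and 77 did not pass the test, and 179 rose when adjusted over the list alone. Their median log2 change was 0.98 (camera adjusted p = 3.02e-35, and adjusted p = 0.151 with an estimated correlation). Ribosomal protein P1 (MSTRG.71467, 7DL) stood at 160 ± 18.0 against 69.9 ± 29.8, and 40S protein S26 (MSTRG.44567, 5AL) at 153 ± 24.5 against 57.4 ± 10.7. The 40S protein S27 (MSTRG.38196, 4BL) rose by 2.03 ± 0.42 on the log2 scale. Of 48 phosphate response genes 26 fell and 2 rose, and 31 fell and 5 rose when adjusted over the list alone. The median log2 change was -0.88 (camera adjusted p = 3.00e-12, and adjusted p = 0.251 with an estimated correlation). Its members that fell included purple acid phosphatases, which release phosphate from organic compounds. The copy MSTRG.37420 on 4AS fell to 63.6 ± 15.4 from 208 ± 35.1. The copy MSTRG.32248 on 3DL fell by 2.64 ± 0.22, and the probable inactive enzyme 16 (MSTRG.23759, 3AL) fell by 3.45 ± 0.18.

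Among 31 starch synthesis genes 7 rose and 2 fell (11 and 2 when adjusted over the list alone, camera adjusted p = 0.0313, and adjusted p = 0.723 with an estimated correlation). Isoamylase 1 (MSTRG.66763, 7AS), which trims branches during starch synthesis, rose by 2.10 ± 0.17 and granule-bound starch synthase 1 (MSTRG.16345, 2BL) rose by 0.91 ± 0.19. Of 41 starch breakdown genes 11 rose and 1 fell (the same counts when adjusted over the list alone, median log2 0.15, but -0.0102 without scaling, camera adjusted p = 0.00948, and adjusted p = 0.640 with an estimated correlation). Glucan phosphorylase MSTRG.47878 on 5BL rose by 1.89 ± 0.20 and beta-amylase MSTRG.28969 on 3B by 0.63 ± 0.18. Of 37 genes of sucrose metabolism and transport 15 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.00021, and adjusted p = 0.251 with an estimated correlation).

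Phenylalanine ammonia-lyase, the entry enzyme of phenylpropanoid synthesis, rose in the copies MSTRG.20466 (2DL, log2 2.67 ± 0.43) and MSTRG.55725 (6AL, log2 2.53 ± 0.21). Of the 20 genes of phenylpropanoids and flavonoids 10 rose and none fell (12 when adjusted over the list alone, camera adjusted p = 3.92e-05, and adjusted p = 0.640 with an estimated correlation). Of 23 jasmonate list genes 9 fell and 2 rose (12 and 2 when adjusted over the list alone, camera adjusted p = 0.00202, and adjusted p = 0.251 with an estimated correlation). The lipoxygenases moved in both directions. The gene MSTRG.58191 on 6AS rose to 10.1 ± 2.21 from 0.295 ± 0.368, while MSTRG.35159 on 4AL and MSTRG.74867 on 7DS fell by 0.99 ± 0.17 and by 1.34 ± 0.18. Xyloglucan endotransglucosylase/hydrolases, which remodel cell walls, also split, with MSTRG.65574 on 7AL up by 3.66 ± 0.40 and MSTRG.18822 on 2DL changed by -4.11 ± 0.39. Of 27 cell wall genes 10 rose and 5 fell (10 and 7 when adjusted over the list alone, camera adjusted p = 0.294).

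Pheophytinase, which removes the phytol tail during chlorophyll breakdown, fell to 36.3 ± 15.1 from 109 ± 33.2 in copy MSTRG.72931 (7DL) and to 29.3 ± 13.2 from 73.3 ± 8.88 in copy MSTRG.64429 (7AL). In all, 3 of 10 genes of chlorophyll breakdown and senescence fell (3 when adjusted over the list alone, camera adjusted p = 0.216). NAC transcription factor 29 (MSTRG.13570, 2AS) fell by 2.21 ± 0.32. Of the NAC genes, 4 of 13 fell (5 when adjusted over the list alone, camera adjusted p = 0.0469, and adjusted p = 0.723 with an estimated correlation). Of 57 genes of autophagy and cysteine proteases 15 fell and 2 rose, and 21 and 2 when adjusted over the list alone (camera adjusted p = 0.00021, and adjusted p = 0.679 with an estimated correlation). The autophagy-related genes MSTRG.10707 (2AL) and MSTRG.14291 (2AS) fell by 1.41 ± 0.31 and by 0.76 ± 0.20, while a member that rose, MSTRG.4037 on 1BL (log2 1.87 ± 0.26), encodes a cysteine proteinase inhibitor. Without the inhibitors and other members matched by accident the list held 42 genes, of which 15 fell and none rose.

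Nitrate reductase (MSTRG.64103, 6DS), the first enzyme of nitrate assimilation, fell to 1.65 ± 0.45 from 36.7 ± 9.23 (log2 -3.81 ± 0.21, adjusted p = 4.78e-05), and the aquaporin TIP2-1 (MSTRG.68301, 7BL) fell by 3.60 ± 0.29. Of 18 genes of nitrogen and amino acid transport 5 fell, also when adjusted over the list alone (camera adjusted p = 0.00169, and adjusted p = 0.251 with an estimated correlation). Among them were the amino acid permease MSTRG.31137 on 3DL (log2 -0.93 ± 0.19) and the NRT1/PTR family 3.1 transporter MSTRG.73830 on 7DS (log2 -1.06 ± 0.13). Of 26 nitrogen assimilation genes 2 rose and 2 fell (camera adjusted p = 0.529), the same counts as in the 20 left without members matched by accident. The branched-chain aminotransferase MSTRG.40739 on 4DL rose by 1.67 ± 0.20. In the list of branched-chain amino acid breakdown and low-sugar markers 7 of 21 genes rose and 1 fell (7 and 5 when adjusted over the list alone, camera adjusted p = 0.529). Protein disulfide isomerase MSTRG.42687 on 4DS rose to 93.9 ± 1.64 from 31.1 ± 1.36. Of the 87 genes of the protein folding list, mainly peptidyl-prolyl and protein disulfide isomerases, 19 rose and 5 fell (21 and 5 when adjusted over the list alone, median log2 0.13, but -0.0201 without scaling, camera adjusted p = 0.014, and adjusted p = 0.251 with an estimated correlation).

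Of 76 light reaction genes 7 rose and none fell (1 when adjusted over the list alone, camera adjusted p = 0.0171, and adjusted p = 0.723 with an estimated correlation). The plastid-encoded photosystem II protein D1 (AIG90408) rose by 3.06 ± 0.90, in libraries where plastid and mitochondrial rRNA also took a larger share of FPKM (7.64% against 1.95%). The chlorophyll a-b binding proteins MSTRG.74451 on 7DS and MSTRG.66153 on 7AS rose by 1.26 ± 0.37 and 1.07 ± 0.31. Of 25 Calvin cycle genes 3 rose (0 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.260). Among the 3 were small subunits of Rubisco MSTRG.20968 on 2DS (log2 1.78 ± 0.52) and MSTRG.17019 on 2BS (log2 1.58 ± 0.44). Of 30 chlorophyll synthesis genes 5 rose and 1 fell (5 and 2 when adjusted over the list alone, camera adjusted p = 0.00349, and adjusted p = 0.723 with an estimated correlation). The remaining lists did not pass camera: photorespiration had 1 of 21 lower, trehalose metabolism 0 of 6, and late embryogenesis genes 1 of 10 higher. Ethylene had 3 higher and 1 lower of 10, cytokinin 2 higher and 1 lower of 6, and auxin 4 higher and 9 lower of 69. Pathogenesis-related proteins had 7 higher and 1 lower of 58, but 1 higher and none lower of 12 without members matched by accident. WRKY factors had 1 lower of 8 and heat shock proteins 2 higher and 1 lower of 31. Likewise histones had 2 higher and 7 lower of 78, the cell cycle list 5 higher of 28, glutathione transferases and peroxidases 6 higher and 8 lower of 56, and lipid transfer and cuticle 1 higher and 4 lower of 23 (of 20 without members matched by accident).

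In this comparison limma called 9884 of 48696 genes, 5255 higher and 4629 lower, of which 3852 changed at least 2-fold. Without scaling the balance turned, with 3621 higher and 7455 lower, as the median of all genes then shifted by -0.15. Of the 82 called genes that the naming rule took, of which only a part is named here, 54 kept their call under every setting fixed before the data were examined. Of these calls 3918 of the higher and 3769 of the lower ones carried a gene name. The count was 5996 without control leaf library 1, 6424 without control library 2 and 5826 without library 2 of the treated leaves. Control leaf libraries 2 and 3 held the nutrient reservoir transcripts given above, and without both of them 3671 genes were called. This fit rests on 1 control library assumed to vary like the other groups and was chosen after seeing the data.

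**Figure D2:**
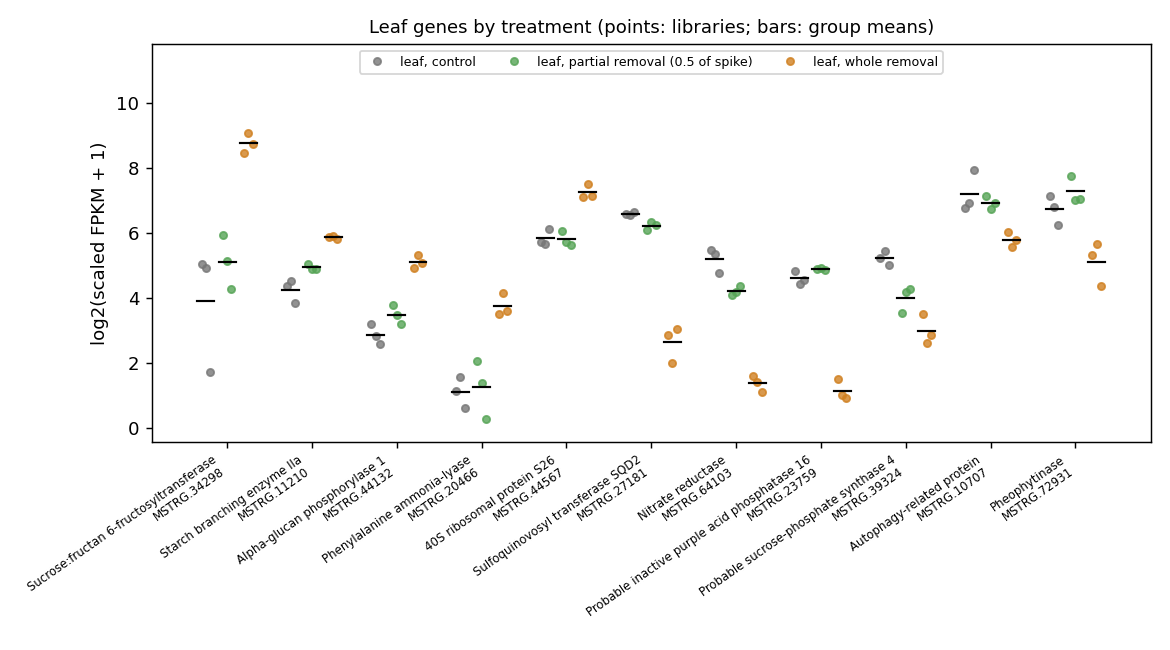
Levels of 11 leaf genes as log2(scaled FPKM + 1) in each library (points) with group means (bars), for control leaves and leaves after partial or whole removal of the spike. Sucrose:fructan 6-fructosyltransferase stood at a mean of 439 scaled FPKM after removal of the whole spike against 21.4 in controls, and SQD2 at 5.54 against 95.5.

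Leaves without the whole spike were also compared directly with leaves that had lost part of it, which asked whether the extent of removal mattered. Sucrose:fructan 6-fructosyltransferase (MSTRG.34298) was higher after whole removal, at 439 ± 91.9 against 37.8 ± 21.0 scaled FPKM (log2 3.63 ± 0.81, adjusted p = 0.0174), but it lost its call without libraries 2 or 3 of either group (adjusted p from 0.0540 to 0.0606). GA2ox5-2 (MSTRG.28563, 3B), of the family that inactivates gibberellins, was higher by 2.41 ± 0.34. The jasmonic acid-amido synthetase JAR1 (MSTRG.7414, 1DL) was higher by 1.67 ± 0.35 and cytokinin dehydrogenase 7 (MSTRG.71845, 7DL), which degrades cytokinins, by 1.65 ± 0.18. Lower after whole removal were glutathione transferase MSTRG.52703 on 5DL (log2 -5.78 ± 1.59), the probable inactive purple acid phosphatases 16 (MSTRG.23759, log2 -3.73 ± 0.18) and 1 (MSTRG.76765, log2 -3.27 ± 0.18), SQD2 (MSTRG.27181, log2 -3.59 ± 0.26) and nitrate reductase MSTRG.64103 (log2 -2.83 ± 0.21). Pheophytinase MSTRG.72931 stood at 36.3 ± 15.1 against 159 ± 50.3 and the photorespiratory serine-glyoxylate aminotransferase MSTRG.70784 on 7BS at 452 ± 37.7 against 857 ± 183.

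Of 226 ribosomal protein genes 140 were higher and none lower (166 and 1 when adjusted over the list alone, camera adjusted p = 3.52e-31, and adjusted p = 0.202 with an estimated correlation). The 40S protein S26 (MSTRG.44567) stood at 153 ± 24.5 against 55.8 ± 9.45. Of 48 phosphate response genes 23 were lower and 2 higher (28 and 3 when adjusted over the list alone, camera adjusted p = 1.02e-11, and adjusted p = 0.368 with an estimated correlation). Of 57 genes of autophagy and cysteine proteases 23 were lower and 2 higher (28 and 3 when adjusted over the list alone, camera adjusted p = 8.50e-07, and adjusted p = 0.592 with an estimated correlation). Of its 42 genes 23 were lower without the members matched by accident. Of 20 genes of phenylpropanoids and flavonoids 10 were higher (12 when adjusted over the list alone, camera adjusted p = 1.12e-05, and adjusted p = 0.592 with an estimated correlation). Of 10 ethylene genes 3 were higher, also when adjusted over the list alone (camera adjusted p = 0.0261, and adjusted p = 0.592 with an estimated correlation). Among them was the ethylene responsive factor 5a (MSTRG.49802, 5BL, log2 0.91 ± 0.17). Limma called 8033 of 48696 genes, 4165 higher and 3868 lower, 2840 of them at least 2-fold. Without scaling rises made up a larger share of the calls. Of the 77 called genes that the naming rule took, of which only a part is named here, 42 kept their call under every setting fixed before the data were examined. The count was 4271 without library 2 of leaves after partial removal, and 4104 and 4659 without libraries 2 and 3 of leaves that lost all of it.

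Both removals shifted 677 genes in the same direction against the same 3 controls, 501 higher and 176 lower, and 3 in opposite directions. Among those with a gene name, 39 were higher and 153 lower in both. Independent lists of these sizes would share 57.7 higher and 25.1 lower genes, which leaves out what the shared controls add. It also leaves out what the larger share of unnamed loci in every treated leaf library may add to the shared rises.

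The comparison of grains from partly removed spikes with control grains asked whether fewer competing grains altered grain transcripts. Few genes passed the test, and neither of the 2 named here as called kept its call when each library was left out in turn. Probable galacturonosyltransferase 11 (MSTRG.39637, 4BS), of the pectin synthesis family, fell to 0.150 ± 0.0913 from 5.06 ± 0.425 scaled FPKM (log2 -2.40 ± 0.27 SE, n = 3 per group, adjusted p = 0.0361). The peroxidase MSTRG.60677 on 6BS fell to 1.72 ± 0.319 from 4.94 ± 0.564 (log2 -1.13 ± 0.12, adjusted p = 0.028). Storage proteins and starch genes did not pass the test one by one, although some had means below control. Gamma-gliadin 2 (MSTRG.10037, 1DS) stood at 380 ± 57.4 against 1073 ± 384 (adjusted p = 0.579) and beta-amylase MSTRG.37812 on 4BL at 251 ± 61.5 against 972 ± 370 (adjusted p = 0.382).

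Over all genes tested, 1 of 94 genes of glutathione transferases and peroxidases fell, and in the other 31 lists limma called 0 genes. Of 17 storage proteins 3 fell when adjusted over the list alone (median log2 -1.43, camera adjusted p = 0.000354, and adjusted p = 0.313 with an estimated correlation). Of 35 starch synthesis genes 4 fell when adjusted over the list alone (camera adjusted p = 8.29e-06, and adjusted p = 0.313 with an estimated correlation). Among 46 starch breakdown genes 5 fell when adjusted over the list alone, and of 39 sucrose genes 2 did (median log2 -0.12, but 0.11 without scaling, camera adjusted p = 0.0186, and adjusted p = 0.346 with an estimated correlation). The 51 genes of cell cycle and DNA replication lay higher (median log2 0.25, camera adjusted p = 2.98e-07, and adjusted p = 0.346 with an estimated correlation), with none called. By camera, lists of the Calvin cycle (median log2 0.73), jasmonate (0.17), chlorophyll synthesis (0.0821) and auxin (0.0700) also lay higher, with adjusted p = 0.505, 0.313, 0.313 and 0.346 with an estimated correlation. The autophagy list lay lower (-0.11, but 0.0750 without scaling, and adjusted p = 0.346 with an estimated correlation). Limma called 13 of 45784 genes, 3 higher and 10 lower, and 2970 had an unadjusted p under 0.05. Without scaling 108 were called, 60 higher and 48 lower, as the median of all genes then shifted by 0.18. The count was 42 and 8 without control grain libraries 2 and 3, and 20 without shaded grain library 2, which enters the shared estimate of the spread.

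The comparison of grains from shaded spikes on plants without leaves with control grains asked how grain transcripts responded to shading and loss of leaves together. A low molecular weight glutenin subunit (MSTRG.6164, 1BS), a gluten storage protein, fell to 68.8 ± 26.0 from 588 ± 176 scaled FPKM (log2 -3.09 ± 0.35 SE, n = 3 per group, adjusted p = 0.00729). Gamma-gliadin 5 (MSTRG.5991, 1BS) fell to 74.8 ± 45.0 from 377 ± 57.1, and globulin 1 (MSTRG.4150, 1BL) to 7.64 ± 2.24 from 56.3 ± 26.7. A plastid starch synthase (MSTRG.3852, 1BL) fell to 1.99 ± 1.29 from 23.1 ± 8.55 (log2 -3.05 ± 0.35, adjusted p = 0.00765). Beta-amylase MSTRG.41026 on 4DL fell to 175 ± 63.4 from 877 ± 356. The defence peptides type-5 thionin (MSTRG.9138) and alpha purothionin (MSTRG.5761, 1BL) fell by 2.72 ± 0.29 and by 2.38 ± 0.47.

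Of 17 measured storage protein genes 3 fell and 14 did not pass the test (4 fell when adjusted over the list alone, median log2 -2.21, camera adjusted p = 0.000237, and adjusted p = 0.285 with an estimated correlation). Of 35 starch synthesis genes 7 fell (14 fell and 2 rose when adjusted over the list alone, camera adjusted p = 0.00453, and adjusted p = 0.366 with an estimated correlation). Among them was glucose-1-phosphate adenylyltransferase MSTRG.74096 on 7DS (log2 -0.74 ± 0.15), which makes the sugar nucleotide for starch. Of 46 starch breakdown genes 4 fell (11 when adjusted over the list alone, camera adjusted p = 0.00159, and adjusted p = 0.285 with an estimated correlation). They included the glucanotransferase DPE1 (MSTRG.21877, 2DS, log2 -1.39 ± 0.19). Of 39 genes of sucrose metabolism and transport 5 fell (10 when adjusted over the list alone, camera adjusted p = 0.00169, and adjusted p = 0.285 with an estimated correlation). The sucrose synthases MSTRG.51537 (5DL), MSTRG.67273 (7AS) and MSTRG.17070 (2BS), which cleave sucrose delivered to the grain, fell by 0.94 ± 0.18, by 0.88 ± 0.16 and by 1.56 ± 0.20.

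The alpha-amylase/trypsin inhibitor CM3 (MSTRG.38762, 4BL) fell by 2.70 ± 0.29, and MOTHER of FT and TFL1 (MSTRG.77705), a regulator of seed dormancy, fell by 2.56 ± 0.31. In the pathogenesis-related list 3 of 63 genes fell (4 when adjusted over the list alone, camera adjusted p = 0.226), and 3 of 21 fell without the members matched by accident, a set that lay lower by camera (median log2 -0.48, adjusted p = 0.00115, and adjusted p = 0.202 with an estimated correlation). Of 94 glutathione transferases and peroxidases 6 fell (8 when adjusted over the list alone, camera adjusted p = 0.00715, and adjusted p = 0.722 with an estimated correlation). The peroxidase MSTRG.57620 on 6AS stood at 0.795 ± 0.120 against 6.24 ± 0.830. Purple acid phosphatase MSTRG.37420 on 4AS fell by 2.44 ± 0.30, caleosin MSTRG.19971 on 2DL, an oil body protein, by 1.39 ± 0.23 and lipoxygenase MSTRG.53511 on 5DL by 1.35 ± 0.25. No gene of the abscisic acid list was called among 5 (camera adjusted p = 0.0237, and adjusted p = 0.285 with an estimated correlation). The 188 ribosomal protein genes lay slightly higher with none called (median log2 0.20, but -0.36 without scaling, camera adjusted p = 0.000338, and adjusted p = 0.768 with an estimated correlation). Lists of histones (median log2 -0.32), lipid transfer and cuticle (-0.26), cell wall (-0.19) and autophagy and cysteine proteases (-0.0844) also lay lower by camera, with adjusted p = 0.742, 0.285, 0.285 and 0.323 with an estimated correlation.

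Rises were fewer and smaller. Diacylglycerol kinase (MSTRG.32514, 3DL), a lipid signalling enzyme, rose to 13.6 ± 1.22 from 6.38 ± 0.457 (log2 0.98 ± 0.13, adjusted p = 0.0109). The expansin EXPA11 (MSTRG.4969, 1BL), which loosens cell walls, rose by 0.92 ± 0.18. Also named by the rule among the rises were the nucleolar GTPase NSN1 (MSTRG.22063, 2DS, log2 0.80 ± 0.12), a putative rRNA methyltransferase (MSTRG.7310, 1DL, log2 0.76 ± 0.12) and RNA polymerase I subunit 1 (MSTRG.34478, 4AL, log2 0.74 ± 0.09). The light receptor phytochrome A (MSTRG.35870, 4AL) rose by 0.74 ± 0.14.

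Limma called 835 of 45784 genes, 149 higher and 686 lower, of which 451 changed at least 2-fold. Without scaling fewer genes were called, and rises made up a smaller share of them. Of the 34 called genes that the naming rule took, of which only a part is named here, 9 kept their call under every setting fixed before the data were examined. Under both no scaling and quantile normalization 12 kept it, and 13 did when each library was left out in turn. The count was 484 and 393 without control grain libraries 1 and 3, 390 and 342 without shaded grain libraries 2 and 3, and 513, 556 and 556 without each library of grains from partly removed spikes. Without control grain library 1 and shaded grain library 2, both high in unnamed loci, 264 genes were called, 20 higher and 244 lower, a setting chosen after seeing the data.

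**Figure D3:**
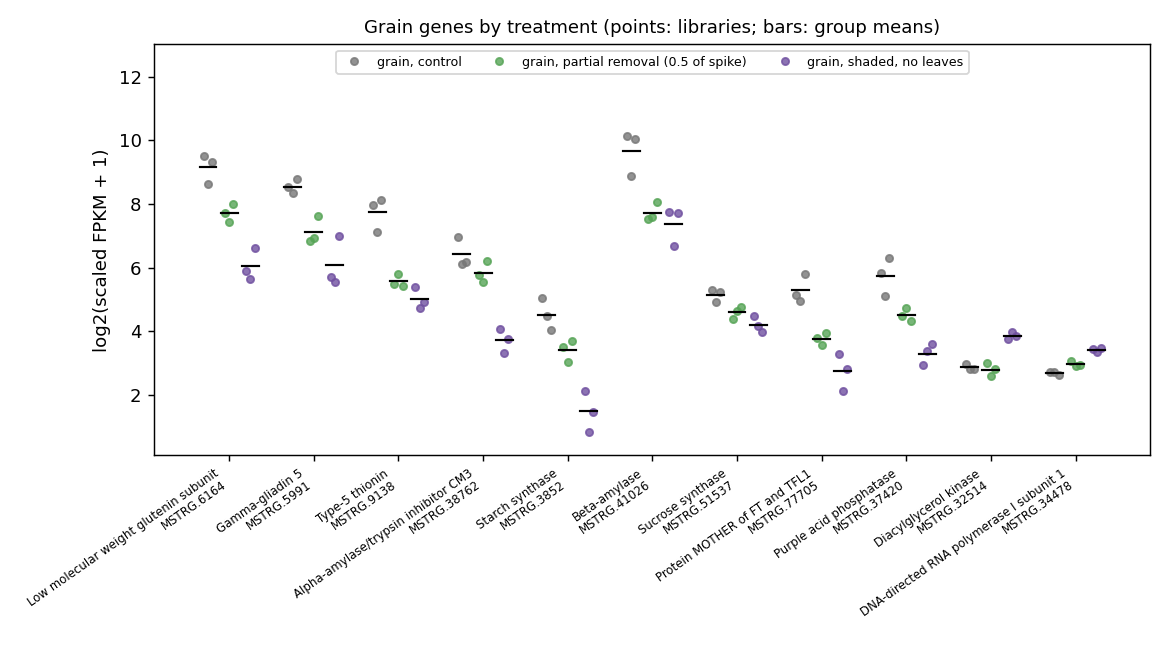
Levels of 11 grain genes as log2(scaled FPKM + 1) in each library (points) with group means (bars), for control grains, grains from partly removed spikes and grains from shaded spikes on plants without leaves. The glutenin subunit MSTRG.6164 stood at a mean of 68.8 scaled FPKM in shaded grains against 588 in controls, and diacylglycerol kinase MSTRG.32514 at 13.6 against 6.38.

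Grains from shaded spikes on plants without leaves were also compared with grains from partly removed spikes. The naming rule took 12 called genes, of which only a part is named here. None of the 12 kept its call when each library was left out in turn, and none changed direction. The sucrose synthase MSTRG.17070 on 2BS was lower in shaded grains, at 1.97 ± 0.495 against 9.76 ± 1.61 scaled FPKM (log2 -1.86 ± 0.20, adjusted p = 0.015). Also lower were the inhibitor CM3 (MSTRG.38762, log2 -2.12 ± 0.29), the lipoxygenases MSTRG.53511 (log2 -1.82 ± 0.25) and MSTRG.44050 on 5AL (log2 -1.49 ± 0.22). The same held for the cytochrome p450 MSTRG.46686 on 5AS (log2 -1.71 ± 0.22), chalcone synthase MSTRG.77302 (log2 -1.15 ± 0.16), the first enzyme of flavonoid synthesis, and the transcription factor bZIP53 (MSTRG.3012, 1AS, log2 -1.19 ± 0.16). The GTPase SAR1 (MSTRG.54444, 5DS), which forms transport vesicles at the endoplasmic reticulum, was higher in shaded grains by 1.26 ± 0.17 and diacylglycerol kinase (MSTRG.32514) by 1.06 ± 0.13.

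Of 51 genes of cell cycle and DNA replication none was called over all genes, while 22 were lower and 1 higher when adjusted over the list alone (median log2 -0.22, camera adjusted p = 4.12e-07, and adjusted p = 0.415 with an estimated correlation). The replication licensing factor MCM3 (MSTRG.522, 1AL), the member with the highest mean, stood at 4.12 ± 0.636 against 10.4 ± 2.05 (adjusted p = 0.211). By camera, lists of the Calvin cycle (median log2 -0.93), abscisic acid (-0.36), trehalose (-0.31), light reactions (-0.31), lipid transfer (-0.23), histones (-0.20), cell wall (-0.19), starch breakdown (-0.19), glutathione transferases and peroxidases (-0.14), pathogenesis-related proteins (-0.12) and auxin (-0.0619) also lay lower. Ribosomal proteins lay higher (0.12, but -0.69 without scaling and -0.11 with quantile normalization). With an estimated correlation none of these 12 lists passed (adjusted p from 0.415 to 0.748). Of 23 jasmonate genes 2 were lower (7 when adjusted over the list alone, camera adjusted p = 4.76e-05, and adjusted p = 0.415 with an estimated correlation). Limma called 87 of 45784 genes, 14 higher and 73 lower, and 65 of them differed at least 2-fold. Without scaling 386 were called, 39 higher and 347 lower. The count was 40 and 21 without shaded grain libraries 2 and 3, and 27, 28 and 30 without libraries 1, 2 and 3 of grains from partly removed spikes.

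In grain, partial removal of the spike and shading with loss of leaves shifted 8 genes in the same direction against the same 3 controls, 2 higher and 6 lower, and none in opposite directions. Independent lists would share 0.00976 higher and 0.150 lower genes, which leaves out what the shared controls add. The count was 35 and 3 without control grain libraries 2 and 3, 14 and 5 without shaded libraries 2 and 3, and 4, 4 and 5 without libraries 1, 2 and 3 of grains from partly removed spikes.

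Partial removal of the spike was the treatment sampled in both tissues, so its effect in leaf was tested against its effect in grain over 12 libraries. Lipoxygenase MSTRG.11562 fell in leaf relative to grain (difference of effects log2 -1.90 ± 0.20 SE, adjusted p = 0.0072). So did the long-chain-alcohol oxidase MSTRG.274 (log2 -2.25 ± 0.32) and aldose 1-epimerase MSTRG.18854 on 2DL (log2 -2.18 ± 0.22), which interconverts sugar anomers. The others named by the rule were galactinol-sucrose galactosyltransferase 6 (MSTRG.77407, log2 -1.35 ± 0.21) and the receptor-like kinase S.2 (MSTRG.46126, 5AL, log2 -1.19 ± 0.15). The jasmonate list had 1 of 15 genes lower and 8 when adjusted over the list alone (median log2 -0.50, camera adjusted p = 1.63e-09, and adjusted p = 0.0158 with an estimated correlation). The 25 starch synthesis genes lay higher in leaf relative to grain, with none called and 8 higher when adjusted over the list alone (median log2 0.41, but -0.00144 without scaling, camera adjusted p = 1.39e-07, and adjusted p = 0.121 with an estimated correlation). Auxin genes lay lower (median log2 -0.22) and autophagy genes higher (0.19, but -0.26 without scaling) by camera, with adjusted p = 0.247 and 0.753 with an estimated correlation. Limma called 27 of 31683 genes, 10 higher and 17 lower, and 5 of the higher ones had no gene name. The largest difference was that of the organelle rRNA rrn26-p (MSTRG.25, log2 6.30), so 6 of the 10 higher calls were unnamed loci or rRNA. Without scaling 4091 were called, 317 higher and 3774 lower. Of the 5 genes named, 2 kept their call under every setting fixed before the data were examined. Regroupings of the libraries within tissue could keep the real leaf groups and so carry the leaf effect, so they cannot decide how often chance alone gives as many calls. In 5 of 100 regroupings, the real one included, as many genes were called, so chance was not excluded for this count. Single libraries moved it as well, to 98 and 15 without control leaf libraries 3 and 2, 15 without control leaf library 1, 14, 12 and 11 without treated leaf libraries 1, 2 and 3, 64 without control grain library 1, and 9, 9 and 10 without treated grain libraries 1, 2 and 3.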

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

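The tests of a bias towards short transcripts, of the libraries with more unnamed loci as a source of the ribosomal rise, of shaded grain library 2, and of scaling for the unnamed loci were chosen after the results they measure were seen. The test of scaling in shaded grain was written before, but its part without scaling was later left out.

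The effect of partial removal of the spike differed between leaf and grain in 27 genes by the interaction test of limma. Regroupings within tissue could keep the real leaf groups and so carry the leaf effect, so they cannot decide how often chance alone gives as many calls. In 5 of 100 drawn regroupings, the real one included, as many genes were called, with 42 as the highest of the others, so chance was not excluded for the count. Lipoxygenase MSTRG.11562 was among them (difference of effects log2 -1.90), from 5.45 to 0.948 scaled FPKM in leaf and from 1.26 to 1.56 in grain, and it passed in each of the 19 settings fixed before the data were examined that tested it (adjusted p from 0.00141 to 0.0402). The jasmonate list, which holds this gene, also differed (median log2 -0.50).

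For the counts of genes called between 3 libraries and 3, 1 of 10 splits, the real one, gave as many calls in each of 6 comparisons. The real counts were 799, 9884 and 8033 in leaf and 13, 835 and 87 in grain, and the highest of the other splits were 10, 8 and 10 in leaf and 7, 5 and 5 in grain. With 10 splits a share under 0.05 cannot be reached.

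Most genes called in leaf after partial removal were loci without a gene name (507 of 799). The calls of these loci depended little on the scaling between libraries, since 506 of the 507 were called in the same direction without scaling and 439 with quantile normalization. That they made up most calls did depend on it. Their share among all calls, the test first written down, was 37.7% without scaling and 59.2% with quantile normalization. RNA that poly(A) selection should have removed, carried over to a different extent, may account for the rises. The 360 of these loci that were higher in leaf and tested in grain stood 4.80 higher on the log2 scale in shaded grain library 2 than in the other 2 shaded libraries (quartiles 4.37 to 5.11), against -0.04 for other unnamed loci. A response of the leaf to partial removal stays open, as the 3 treated libraries all carry it. Leaves after whole removal had a similar share of FPKM on unnamed loci (mean 30.9%, against 29.7% after partial removal and 15.9% in controls). Treated leaf libraries thus differed from controls in this share after both removals. Treatment therefore cannot be told apart here from a difference in library preparation.

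After whole removal, 149 of 226 ribosomal protein genes rose and 26 of 48 phosphate response genes fell, and neither list passed camera with an estimated correlation (adjusted p = 0.151 and adjusted p = 0.251). Both passed limma fry (adjusted p = 0.000295 and adjusted p = 0.000371), which does not compare a list with other genes. Genes of histones, of lipid transfer and cuticle, and with thioredoxin in their description did not rise as a set. Their median log2 change was -0.0417 over 131 genes (quartiles -0.38 to 0.19) against 0.98 for ribosomal proteins. This argues against a bias towards short transcripts only so far as these genes are short, since lengths were not used. The larger share of unnamed loci and organelle rRNA is argued against by leaves after partial removal, which had as large a share and a median of 0.0837 in the ribosomal list. Grain RNA in control leaf libraries 2 and 3, estimated at 1.62%, could account for at least 0.5 of the fall in 0% of the 26 phosphate response genes that fell. The tests of short transcripts and of unnamed loci bear on the ribosomal rise, and the test of grain RNA on the phosphate response alone. A response to removal of the whole spike may underlie both changes but stays a hypothesis, found and tested on the same data. Loss of the sink and the cutting itself cannot be told apart in it.

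In shaded grain, falls outnumbered rises (686 against 149). Shaded grain library 2 as the source is argued against by the genes called anew without it, of which 43 rose and 347 fell (11.03% rises, against 17.8% with it). The share of rises with quantile normalization, 20.7%, argues against the choice between these ways of scaling as the source. It cannot exclude an error common to both. The test as first written also asked for the share without scaling. That part was left out, since the median of all genes then shifts by -0.31. The number of calls did depend on single libraries and was 390 without shaded grain library 2. Other explanations of the falls, reduced supply and loss of light on the spike among them, were not tested.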

How the results depend on the processing

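The weights per library, the 2 settings that left out pairs of libraries and the changed lists were chosen after seeing the data. For settings not explained by fewer genes or fewer libraries, the cause was not tested. Counts of calls are given in the order leaf partial, leaf whole, leaf whole against partial, grain partial, grain shaded, grain shaded against partial, and leaf against grain effect, where the counts as reported were 799, 9884, 8033, 13, 835, 87 and 27. Counts that moved by over 1.5 times are listed, and the others stayed within that.

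Leaving out each library in turn gave 186 to 850, 5826 to 9762, 4104 to 9683, 8 to 42, 342 to 618, 21 to 127 and 9 to 98 calls. It gave 154 to 754 genes shared in leaf and 3 to 35 in grain, against 677 and 8. The lists called by camera ranged from 10 to 13, 8 to 14, 5 to 8, 7 to 15, 8 to 15 and 4 to 15, against 10, 13, 5, 9, 11 and 14. The libraries that moved a count of calls by over 1.5 times are named beside it in the report. The genes shared in leaf were 154 and 166 without control libraries 1 and 2, and 376, 304 and 236 without libraries 1, 2 and 3 of partial removal.

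Without scaling, 2046 genes were called in leaf after partial removal, 108 in grain after partial removal, 510 in shaded grain, 386 between the treated grains and 4091 between tissues, with 1425 and 33 shared in leaf and grain, and 9 and 8 lists for the direct comparisons in leaf and grain. The median of all genes then shifted by -0.23, -0.15, 0.08, 0.18, -0.31, -0.49 and -0.43 in the order above, and the share of rises among calls was 28.2%, 32.7%, 65.6%, 55.6%, 6.47%, 10.1% and 7.75%, against 67.0%, 53.2%, 51.8%, 23.1%, 17.8%, 16.1% and 37.0% as reported. Changes are therefore relative to the median gene. Quantile normalization gave 71 calls between tissues and 6 lists in leaf after partial removal. With it the Calvin cycle list in leaf after partial removal changed its median to -0.0441, and the ribosomal list in shaded against partly removed grain to -0.11.

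A pseudocount of 0.1 gave 16 calls between tissues. No filter gave 360 calls in leaf after partial removal, 7 in grain after partial removal, 375 in shaded grain, 22 between treated grains and 205 between tissues. A filter at an FPKM of 5, which tests fewer genes, gave 508, 5467 and 4512 in leaf and 5 in grain after partial removal. Named loci only gave 131 calls in leaf after partial removal. Only the libraries of the groups compared, which are fewer, gave 309 in that comparison and 210 in shaded grain. Library weights gave 5360, 16809, 20 and 1487 calls in leaf after partial removal, between treated leaves, in grain after partial removal and between tissues. Library 2 of partial removal in leaf had a weight of 10.4 there.

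With the library number as a replicate block, 655, 8296, 6752, 2, 388, 13 and 8 genes were called. Within a tissue the numbers do not pair the samples as far as the values show. The correlation of residuals between libraries of the same number was above 0.1 in 1 of 9 pairs in leaf and 0 of 9 in grain. Leaf and grain libraries of the same number were not compared with each other.

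With an estimated correlation, camera called 1 list in leaf after partial removal and 1 between tissues, and 0 in the other 5 tests. Fry called 4 lists in leaf after partial removal, 12 between treated leaves, 7 in shaded grain and 0 in the other 2 grain comparisons. Without control leaf libraries 2 and 3, 438 and 3671 genes were called against the remaining control, assumed to vary like the other groups, and without control grain library 1 and shaded grain library 2, 20, 264 and 53 genes were called in grain. Of the called genes that the naming rule took, not all of them named in the text, 5 of 14, 54 of 82, 42 of 77, 0 of 2, 9 of 34, 0 of 12 and 2 of 5 kept their call. This holds for every setting fixed before the data were examined, and no direction was reversed. Depth is unknown, so no limit from counting reads can be given.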

Other observations

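The GO terms tested here were chosen after the data were seen, and so was the test of reserve genes in grain after partial removal. Medians had the same sign without scaling and with quantile normalization except where stated. With an estimated correlation, camera called 0 of 522 GO terms in leaf and 0 of 508 in grain in any comparison, against 52 to 146 with the preset correlation. Enzymes with acid phosphatase activity fell in leaf after whole removal (31 of 58 genes lower and 3 higher, median log2 -0.72, camera adjusted p = 2.17e-11, and adjusted p = 0.523 with an estimated correlation). Of 29 genes of branched-chain amino acid biosynthesis 15 rose and none fell (camera adjusted p = 5.52e-05, and adjusted p = 0.540 with an estimated correlation). Of 250 thylakoid genes 54 rose and 3 fell (camera adjusted p = 2.70e-05, and adjusted p = 0.891 with an estimated correlation), and of 53 genes of mitochondrial complex I 7 rose and none fell (camera adjusted p = 4.65e-06, and adjusted p = 0.724 with an estimated correlation). Lipid metabolism genes went the other way, with 61 of 241 lower and 9 higher (camera adjusted p = 0.00053, and adjusted p = 0.523 with an estimated correlation). How many of the thylakoid and complex I genes are encoded in organelles was not examined. Plastid and mitochondrial rRNA took 7.64% of FPKM in leaves after whole removal against 1.95% in controls.

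In shaded grain, 13 of 54 genes with nutrient reservoir activity fell and none rose (median log2 -0.67, camera adjusted p = 3.06e-06, and adjusted p = 0.334 with an estimated correlation). Of 90 ribosome biogenesis genes 6 rose and none fell (median log2 0.32, but -0.16 without scaling, camera adjusted p = 1.05e-14, and adjusted p = 0.438 with an estimated correlation). In grain after partial removal, the 21 genes of DNA replication initiation had a median log2 change of 0.77 (camera adjusted p = 4.94e-11, and adjusted p = 0.891 with an estimated correlation), with limma calling 0 of them and 5 at an unadjusted p under 0.05. Storage protein transcripts made up 1.15% ± 0.0825 (SD, n = 3) of FPKM in control grain, 0.597% ± 0.0787 after partial removal and 0.264% ± 0.217 in shaded grain, the last including shaded grain library 2 at 0.0221%. Transcripts annotated with nutrient reservoir activity, a wider set, made up 5.12% ± 1.15, 5.36% ± 0.225 and 3.04% ± 2.25 in the same groups. Control grain library 1, with 55.4% of FPKM on unnamed loci, stood at 3.80%, and control libraries 2 and 3 at 5.63% and 5.93%, above each library of partial removal (5.10%, 5.45% and 5.52%). Of the FPKM on named loci alone, a measure added after the data were seen, the share was 8.53%, 7.74% and 7.93% in the control libraries and 7.45%, 7.38% and 7.29% after partial removal. In shaded grain it was 6.91%, 6.08% and 5.48%, where library 2 had 0.613% of all FPKM.

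Grain after partial removal may share part of the fall in reserve genes seen in shaded grain. Of 19 storage, starch and sucrose genes that fell in shaded grain, a share of 0.895 had a negative log2 change after partial removal, with a median of -0.68 against -1.39. In 20 simulations without an effect of partial removal but with shared controls drawn anew, this share averaged 0.502 and reached at most 0.688. They took the real control means as true, so control values high by chance, which helped to choose the 19 genes, are not in them. Such values would make both changes negative, so the simulations cannot exclude the shared controls as a source of the share. The simulated noise was independent between genes, and genes of one grain library move together, so the share is weaker evidence than these simulations make it.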
